A study of Homo sapiens with 9 samples.

How the data were processed

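Total RNA from BT549 cells was sequenced in 9 libraries, 3 each after transfection with control siRNA, siRNA against Fra-1 and siRNA against DDX5. The authors converted and processed the reads with bcl2fastq 2.17.1.14 and CASAVA and quantified transcripts with Cufflinks 2.1.1 on GRCh37, per the labels. The deposited files list 214293 Ensembl transcripts of 63655 genes per library with FPKM (fragments corrected for transcript length and library size) as scaled by the authors. They also hold confidence bounds and the coverage per base. The aligner, the annotation release and the siRNA sequences are not given in the sources used here. FPKM sums ran from 749033 to 891913 per library.

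Gene FPKM was the sum over the transcripts of a gene. Symbols and types came from GENCODE, matched by stable identifier, for 52515 genes (82.5%), and coordinates came from the files. A set of 25 genes whose transcripts are listed in pieces was left out. Of 24045 genes above 0 in at least 1 library, the 13081 with at least 1 FPKM in at least 3 of the 9 libraries were tested, 11040 of them protein-coding.

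Log2 of FPKM plus 0.5 was analysed with limma 3.58.1 in R 4.3.3, with all 9 libraries in one fit and a mean-variance trend. Comparisons were siFra-1 against siControl, siDDX5 against siControl and siDDX5 against siFra-1, with Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The 6 residual degrees of freedom were joined by 4.01 prior degrees of freedom. A fold is taken from the difference of mean log2 values. Target genes also had exact permutation tests of 3 against 3 libraries, two-sided. Of 36 gene lists, 33 had at least 4 tested members and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Some lists share members, so their calls are not independent. For example, FN1 is in the matrix and mesenchymal lists, BIRC3 in the apoptosis and NF-kB lists and ACTA2 in the mesenchymal and basal lists. Transcript shares of genes with a mean of at least 5 FPKM were tested with limma on the arcsine of the square root, for mean shares from 0.05 to 0.95.

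The gene lists, the main tests of genes, lists and transcript shares, the filter and the rule for named genes were set before the data were examined. The rule took FOSL1, DDX5, DDX17 and the FOS and JUN members always. It then took up to 10 genes with the largest rises and 10 with the largest falls per knockdown, and up to 5 each way for the difference. These came from called protein-coding genes whose replicates do not overlap. From each list it took up to 4 called members with the smallest p, without those conditions on type and overlap. Up to 5 genes changed in both knockdowns in each way, 3 changed in opposite ways and the 5 transcripts with the largest change in share were added. Genes of uncertain mapping and further list members are summarised as counts.

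Alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 5 FPKM, upper quartile, sum and quantile scaling, the replicate number as a block, only the 2 groups compared, no trend, array weights, protein-coding genes only and leaving out each library in turn. With a library left out, its group of 2 borrows its spread from the other groups. Another 7 alternatives were chosen after seeing the data: without genes listed at 0 in some library, with the genes in pieces, with a GC trend removed from each library by a spline with 5 degrees of freedom, leaving out 3 libraries that deviate together, lists without the targeted genes, scaling to a sum that leaves out 5S and 5.8S rRNA genes, and separate controls for the knockdowns. In the last, 1 control served one knockdown and 2 the other, each set as its own group in the fit, with the spread of a lone control taken from the other groups.

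The gene test was tested on simulated data at the measured spread. It recovered 18 of 67 genes changed by 0.5 on the log2 scale (26.9%), 59 of 67 changed by 1 (88.1%) and 66 of 66 changed by 2, and called 8 unchanged genes. Of 33 simulated lists, 1 lowered list was called, and 0 were called with none changed. Genes were simulated as independent, while the estimated correlation within real lists reached 0.536. The 0 therefore says nothing about false calls in lists of correlated genes. Of 200 moved transcripts 143 were recovered, and 6 unmoved transcripts were called.

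For sequence tests, every 7-mer present in the 3′ UTR of at least 100 genes was set against the fold changes, limited to 3 either way, of 10923 protein-coding genes with a 3′ UTR of at least 50 bases (98.9%). The fold changes were shuffled 100 times, and the test was repeated after removal of a polynomial trend with GC content of the transcripts. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.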

Results

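RNA was sequenced from BT549 cells, a human breast cancer line that lacks estrogen receptor alpha, after transfection with a control siRNA, an siRNA against Fra-1 or an siRNA against DDX5. Fra-1 is the AP-1 transcription factor encoded by FOSL1, and DDX5 is a DEAD-box RNA helicase that the series title names as its coactivator. Each of the 3 groups held 3 libraries. Read counts are not given in the sources used here. The bases assigned to transcripts, as coverage times length, came to 5.67, 4.03 and 4.74 gigabases in siControl replicates 1 to 3. They came to 5.30, 5.799 and 4.98 gigabases in siFra-1 and to 5.21, 5.77 and 4.84 gigabases in siDDX5. Between 12520 and 12819 genes per library reached 1 FPKM, and 13081 genes were tested. Log2 levels correlated at 0.976 to 0.987 between libraries of a group and at 0.959 to 0.977 between libraries of different groups. The median standard error (SE) of a log2 fold change was 0.136. Whether the replicates were separate cultures is not stated, so the p-values measure only the spread between these samples.

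The targeted transcripts were compared across the groups to ask whether each siRNA lowered its own target. FOSL1 (ENSG00000175592, chromosome 11, 65659520 to 65668044, GRCh37) fell from 178 ± 13.7 FPKM in siControl to 36.8 ± 4.2 FPKM in siFra-1 (mean ± SD, n = 3 per group, limma adjusted p = 2.22e-06), which is 79.3% lower. DDX5 (ENSG00000108654, chromosome 17, 62495734 to 62504317) fell from 259.8 ± 19.7 FPKM to 12.8 ± 1.18 FPKM in siDDX5, which is 95.0% lower (adjusted p = 5.55e-09). For the other target neither siRNA gave an adjusted p under the threshold. FOSL1 stood at 150.2 ± 6.06 FPKM in siDDX5 (log2 fold change -0.24, adjusted p = 0.0969), and DDX5 stood at 245 ± 22.4 FPKM in siFra-1 (adjusted p = 0.568). For each target against its own siRNA the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, and it was also 0.1 for FOSL1 in siDDX5 and 0.5 for DDX5 in siFra-1. DDX17 (ENSG00000100201), the closest paralog of DDX5, rose from 69.7 ± 4.85 to 101.4 ± 1.98 FPKM in siDDX5 (log2 fold change 0.54, adjusted p = 0.00241) and stood at 79.2 ± 7.28 FPKM in siFra-1 (adjusted p = 0.16). DDX17 differed between the knockdowns by 0.36 (adjusted p = 0.0184). That call was lost without siFra-1 replicate 2 (adjusted p = 0.051), siFra-1 replicate 3 (0.0683), siDDX5 replicate 1 (0.0568) or siDDX5 replicate 3 (0.0686), and without 3 libraries that deviate together, siControl replicate 1, siFra-1 replicate 2 and siDDX5 replicate 2 (0.0971).

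**Figure D1:**
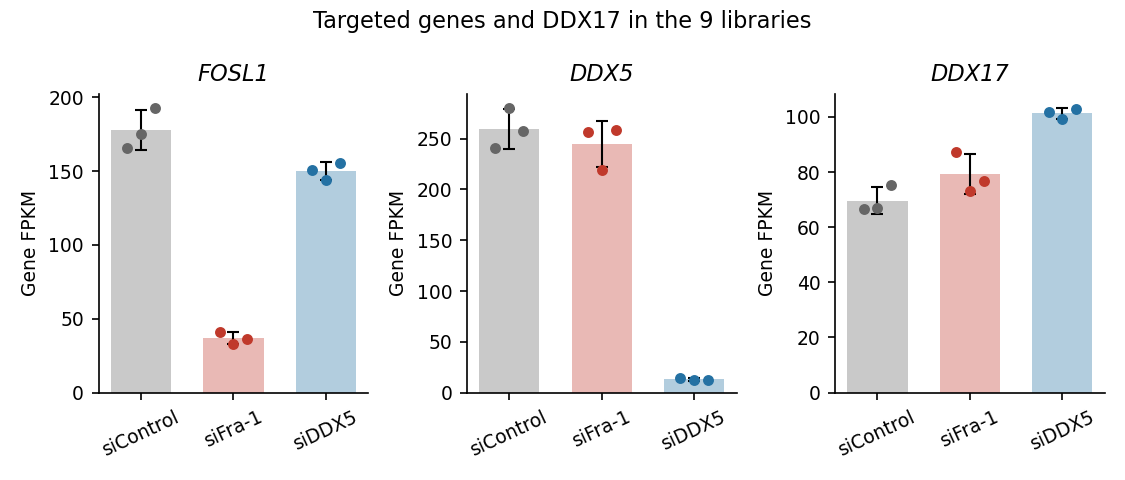
FPKM of FOSL1, DDX5 and DDX17 in siControl, siFra-1 and siDDX5 libraries. Bars are group means, error bars are SD, and points are the 3 libraries of a group; FOSL1 averaged 36.8 FPKM in siFra-1 against 178 FPKM in siControl, and DDX5 12.8 FPKM in siDDX5 against 259.8 FPKM.

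Loss of Fra-1 was compared with siControl to find the genes that follow this transcription factor. Interferon-induced genes were among the largest rises. OAS2 (ENSG00000111335, chromosome 12, 113416200 to 113449528), an oligoadenylate synthetase that senses duplex RNA, rose 8.13-fold, from 9.55 ± 1.22 to 81.1 ± 8.5 FPKM (n = 3 per group, adjusted p = 1.76e-06). IFI27 rose 8.72-fold, the chemokine CXCL10 7.87-fold and the leukocyte adhesion receptor VCAM1 7.07-fold. Among the genes that fell, CDKN2C (ENSG00000123080, chromosome 1, 51426417 to 51440305), an inhibitor of the cell cycle kinases CDK4 and CDK6, dropped from 92.5 ± 6.7 to 23.6 ± 2.46 FPKM (log2 fold change -1.95, SE 0.0908, adjusted p = 2.28e-06). ANAPC13, a subunit of the anaphase-promoting complex, fell by 1.87 on the log2 scale and the actin-binding CAP2 fell by 1.84. The 3′ UTRs of CDKN2C, ANAPC13 and CAP2 each held the 7-mer GAGTAGC, which also occurs in the FOSL1 mRNA. Those of TAGLN, EOMES and GEM did not hold it, nor did those of BAALC, HOPX and NTSR1, also among the largest falls. Of all genes searched, 8.2% held it. The smooth muscle gene TAGLN fell from 113 ± 15.1 to 32.0 ± 4.6 FPKM, the T-box factor EOMES fell by 1.78 and the small GTPase GEM fell by 1.69.

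Among 27 interferon response genes, 26 rose, 0 fell and 1 did not pass, and 27 changed when adjusted over the list alone. Their mean log2 fold change was 2.07 (camera adjusted p = 1.83e-31; adjusted p = 0.211 with an estimated correlation). IFI44 rose from 19.1 ± 2.21 to 103.9 ± 13.5 FPKM. Of 20 collagen and matrix genes, 15 rose, 1 fell and 4 did not pass, and 16 changed when adjusted over the list alone (mean 0.63, camera adjusted p = 2.64e-08; adjusted p = 0.38 with an estimated correlation). Fibronectin, FN1, rose from 98.2 ± 2.47 to 193 ± 5.93 FPKM, COL1A2 from 191 ± 16.6 to 328 ± 8.18 FPKM and periostin, POSTN, from 3.35 ± 0.349 to 8.06 ± 0.598 FPKM. TGF-beta targets rose in 11 of 17 cases, with 0 lower, 6 not passed and 12 changed when adjusted over the list alone (mean 0.78, camera adjusted p = 2.64e-08; adjusted p = 0.211 with an estimated correlation). TGFBI, a matrix protein, rose from 69.4 ± 15.3 to 212 ± 5.64 FPKM and the transcription factor BHLHE40 from 9.16 ± 1.44 to 26.0 ± 1.6 FPKM. Luminal breast markers rose in 4 of 5 tested genes, also 4 when adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 0.000375; adjusted p = 0.211 with an estimated correlation). The mean of the luminal list was 1.145, and 0.60 with no filter on low values. The keratins KRT18 (3.48 ± 0.883 to 15.4 ± 1.56 FPKM) and KRT8 (1.74 ± 0.505 to 7.72 ± 1.63 FPKM) rose, as did the mucin MUC1.

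Of 23 cytokines and NF-kB targets in siFra-1, 11 rose, 2 fell, 10 did not pass and 18 changed when adjusted over the list alone (mean 0.33, camera adjusted p = 0.0164; adjusted p = 0.441 with an estimated correlation). The macrophage growth factor CSF1 rose from 58.0 ± 3.7 to 161 ± 26.4 FPKM and TNF rose 3.40-fold, while IL1B fell from 18.7 ± 0.767 to 9.66 ± 1.19 FPKM. Apoptosis regulators rose in 8 of 19 cases and fell in 1, with 11 changed when adjusted over the list alone (mean 0.25, camera adjusted p = 0.0197; adjusted p = 0.441 with an estimated correlation). They included the inhibitor BIRC3 (35.5 ± 6.9 to 81.1 ± 12.7 FPKM). EGFR and MAPK feedback genes rose in 5 of 18 cases and fell in 1, with 7 changed when adjusted over the list alone (mean 0.33, camera adjusted p = 0.0167; adjusted p = 0.441 with an estimated correlation). SPRY1 rose from 7.99 ± 0.471 to 26.5 ± 1.19 FPKM and SPRY2 from 21.5 ± 3.96 to 50.2 ± 3.61 FPKM, both inhibitors of receptor tyrosine kinase signalling. Mesenchymal markers rose in 7 of 14 cases and fell in 3, with 11 changed when adjusted over the list alone (mean 0.22, camera adjusted p = 0.0476; adjusted p = 0.441 with an estimated correlation). The EGFR list's call ended without siControl replicate 1 (adjusted p = 0.0732), and the mesenchymal call ended without siControl replicate 1 (0.0579), siControl replicate 2 (0.06), siFra-1 replicate 2 (0.178) or siDDX5 replicate 3 (0.0525). The mesenchymal call also ended after scaling to one sum (0.0541, or 0.0934 with 5S and 5.8S rRNA left out of the sum), with no trend (0.0649), with array weights (0.0997), with protein-coding genes only (0.0682) and without the 3 libraries that deviate together (mean 0.14, adjusted p = 0.24).

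Cytosolic ribosomal protein genes fell in 10 of 32 cases in siFra-1, with 0 higher, 22 not passed and 18 changed when adjusted over the list alone (mean -0.25, camera adjusted p = 8.53e-08; adjusted p = 0.441 with an estimated correlation). RPS2 fell from 487 ± 51.1 to 346 ± 39 FPKM, and the mean of the list was -0.14 after quantile normalisation. Respiratory chain genes fell in 7 of 25 cases, with 8 when adjusted over the list alone (mean -0.21, camera adjusted p = 3.66e-05; adjusted p = 0.441 with an estimated correlation). UQCRC2 of complex III fell from 87.3 ± 6.72 to 62.2 ± 1.59 FPKM and ATP5PO of the ATP synthase from 245 ± 28.6 to 174 ± 9.53 FPKM. Ribosome biogenesis genes fell in 5 of 24 cases, also 5 when adjusted over the list alone (mean -0.16, camera adjusted p = 0.0164; adjusted p = 0.335 with an estimated correlation), and the nucleolar NOLC1 fell from 132 ± 8.08 to 54.2 ± 2.39 FPKM. G2/M and mitosis genes fell in 7 of 32 cases, with 9 when adjusted over the list alone (mean -0.16, camera adjusted p = 0.00574; adjusted p = 0.482 with an estimated correlation). The mitotic kinase NEK2 fell from 30.6 ± 2.99 to 14.0 ± 2.22 FPKM and UBE2C from 289 ± 25.1 to 215 ± 2.78 FPKM. Without siFra-1 replicate 2 the calls of the G2/M list (mean -0.09, adjusted p = 0.2) and the ribosome biogenesis list (adjusted p = 0.0624) ended, and quantile normalisation also ended the latter (adjusted p = 0.069). The G2/M call further ended in fry (0.101) and without the 3 libraries that deviate together (mean -0.08, adjusted p = 0.24). Of the 4 members with the smallest p in each list, 1 ribosomal protein gene, 2 respiratory chain genes, 1 ribosome biogenesis gene and 2 G2/M genes kept their calls under all alternatives. Scaling to one sum without 5S and 5.8S rRNA gave means of -0.13 for the respiratory chain, -0.08 for ribosome biogenesis and -0.08 for G2/M, all still called.

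Genes tied to AP-1 itself went both ways. Of 26 listed AP-1 and Fra-1 invasion targets 22 were tested, of which 7 rose, 8 fell and 7 did not pass, and 15 changed when adjusted over the list alone (mean log2 fold change 0.016, camera adjusted p = 0.811 in the downward direction). The receptor kinase AXL fell from 74.8 ± 7.92 to 37.6 ± 2.43 FPKM, the collagenase MMP1 from 25.9 ± 1.64 to 15.6 ± 0.692 FPKM and S100A2 from 70.4 ± 2.54 to 38.9 ± 4.43 FPKM. Thrombospondin, THBS1, rose from 216 ± 18.6 to 346 ± 12 FPKM. In the AP-1 family, 2 of 13 members rose and 2 fell, counting FOSL1, and 7 changed when adjusted over the list alone (mean -0.07, median 0.08, camera adjusted p = 0.884). FOS rose from 1.20 ± 0.159 to 2.56 ± 0.838 FPKM (log2 fold change 0.82, SE 0.204, adjusted p = 0.021). That call was lost without siControl replicate 1 (adjusted p = 0.0611), siControl replicate 3 (0.0543) or siFra-1 replicate 3 (0.0765), and with no filter on low values (0.0528) or without the 3 libraries that deviate together (0.13). The other FOS and JUN genes of the list did not pass in siFra-1: FOSL2 had a log2 fold change of 0.16 (adjusted p = 0.311), FOSB 0.09 (0.783), JUN 0.32 (0.0838), JUNB 0.44 (0.477) and JUND -0.06 (0.836). No call among these 5 genes or FOS was made in siDDX5, where the FOS value was 1.70 ± 0.163 FPKM (adjusted p = 0.219).

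In all, 2508 of 13081 genes changed in siFra-1 at an adjusted p under 0.05 in limma, 1440 higher and 1068 lower. At least 2-fold changes numbered 399, with 308 higher and 91 lower, and 251 among genes with a mean of at least 5 FPKM. The count fell to 1472 without siControl replicate 1, 1623 without siFra-1 replicate 1 and 1415 without siFra-1 replicate 3, and to 1191 without the 3 libraries that deviate together; the same step left 1112 genes in siDDX5 and 1132 between the knockdowns. Scaling to one sum gave 1716 in siFra-1, and 2502 with 5S and 5.8S rRNA left out of the sum. Removing a GC trend from each library gave 3672 in siFra-1, 3865 in siDDX5 and 3530 between the knockdowns. Of the changed genes 57.4% were higher, against 55.3%, 61.4% and 53.4% after upper quartile, sum and quantile scaling and 73.9% after scaling to a sum without 5S and 5.8S rRNA. No list call in any of the 3 comparisons held with an estimated correlation in camera.

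Loss of DDX5 was compared with siControl to ask which genes follow the helicase. Interferon-induced genes were again among the largest rises. IFIT1 (ENSG00000185745, chromosome 10, 91152303 to 91163745), an interferon-induced RNA-binding protein, rose 9.43-fold from 24.0 ± 7.59 to 224 ± 14.5 FPKM (n = 3 per group, adjusted p = 8.77e-06). IFI44L rose 8.87-fold, IFIT2 8.69-fold and the GTPase MX1 from 35.4 ± 7.1 to 244 ± 12.1 FPKM. IFNB1 (ENSG00000171855, chromosome 9, 21077104 to 21077943), which encodes interferon beta, rose 6.59-fold from 1.91 ± 0.397 to 15.2 ± 1.46 FPKM (adjusted p = 5.22e-05). GNPAT (ENSG00000116906, chromosome 1, 231376953 to 231413719), a peroxisomal enzyme of ether lipid synthesis, fell from 27.6 ± 2.52 to 4.003 ± 0.373 FPKM (log2 fold change -2.64, SE 0.107, adjusted p = 7.75e-07). The mitochondrial import factor TOMM34 fell by 1.54 on the log2 scale, the copper chaperone ATOX1 fell by 1.31, the adenylate kinase AK3 fell by 1.30 and the signalling kinase IRAK1 fell by 1.27. The 3′ UTRs of TOMM34, AK3 and IRAK1 held the 7-mer GTCCTTG, which also occurs in the DDX5 mRNA. Those of GNPAT, ATOX1, PAICS, POLR2J2, TMEM184B and TMEM56-RWDD3 did not hold it, and 9.33% of all genes searched did. The purine synthesis gene PAICS (ENSG00000128050) was listed at 0 in all 3 siDDX5 libraries, at 129, 148 and 133 FPKM in siControl and at 130.3, 111.2 and 137 FPKM in siFra-1; whether the 0 comes from the cells or from the quantification is not decided. POLR2J2, a gene with near-identical copies, and the readthrough gene TMEM56-RWDD3 had log2 fold changes of -1.59 and -1.37, but neither call held. POLR2J2 was lost without siControl replicate 1 (adjusted p = 0.101), siControl replicate 3 (0.0707), siDDX5 replicate 1 (0.0991) or siDDX5 replicate 3 (0.101), and TMEM56-RWDD3 without siControl replicate 1 (0.0649), 2 (0.0579) or 3 (0.0831). The TMEM56-RWDD3 value was -0.87 without siDDX5 replicate 3.

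All 27 interferon response genes rose in siDDX5, also 27 when adjusted over the list alone (mean log2 fold change 2.26, camera adjusted p = 8.34e-38; adjusted p = 0.144 with an estimated correlation). Of 32 G2/M and mitosis genes, 0 rose, 29 fell and 3 did not pass, and 32 changed when adjusted over the list alone (mean -0.70, camera adjusted p = 1.64e-19; adjusted p = 0.171 with an estimated correlation). The ubiquitin-conjugating enzyme UBE2C fell from 289 ± 25.1 to 157 ± 4.7 FPKM, the mitotic kinase AURKB from 95.1 ± 7 to 50.9 ± 3.29 FPKM and the kinetochore protein CENPF from 32.6 ± 4.1 to 13.3 ± 1.07 FPKM. Of 33 G1/S and DNA replication genes, 0 rose, 22 fell and 11 did not pass, and 28 changed when adjusted over the list alone (mean -0.46, camera adjusted p = 3.13e-10; adjusted p = 0.145 with an estimated correlation). The replication factor CDC45 fell from 26.2 ± 0.763 to 12.9 ± 0.374 FPKM, the ribonucleotide reductase subunit RRM2 from 79.3 ± 2.6 to 47.3 ± 4.16 FPKM and the sliding clamp PCNA from 204 ± 22.3 to 133 ± 5.05 FPKM. Respiratory chain genes fell in 9 of 25 cases, with 10 when adjusted over the list alone (mean -0.21, camera adjusted p = 0.00126; adjusted p = 0.313 with an estimated correlation), among them UQCRC2, whose call ended after scaling to one sum (adjusted p = 0.0618), though not with 5S and 5.8S rRNA left out of the sum, and without the 3 libraries that deviate together (0.0828). Ribosome biogenesis genes fell in 9 of 24 cases, with 12 when adjusted over the list alone (mean -0.22, camera adjusted p = 0.00126; adjusted p = 0.145 with an estimated correlation), including NOP56, whose call ended without those 3 libraries (0.0722). Of the 4 members with the smallest p, 0 respiratory chain and 1 ribosome biogenesis genes kept their calls under all alternatives. Among 32 DEAD-box helicases, 2 rose, 10 fell, counting DDX5, and 16 changed when adjusted over the list alone (mean -0.32, camera adjusted p = 0.00391; adjusted p = 0.19 with an estimated correlation). Without DDX5 itself the mean of the list was -0.19 (camera adjusted p = 0.0172). The mRNA export factor DDX39A fell from 105.3 ± 12.5 to 58.6 ± 6 FPKM.

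Collagen and matrix genes rose in 12 of 20 cases in siDDX5, with 0 lower and 14 changed when adjusted over the list alone (mean 0.43, camera adjusted p = 1.45e-07; adjusted p = 0.23 with an estimated correlation). COL3A1 rose from 60.3 ± 3.36 to 137 ± 11.2 FPKM and the matrix protein SPARC from 489 ± 35.9 to 895 ± 46.1 FPKM. Integrins and adhesion genes rose in 8 of 19 cases and fell in 3, with 13 changed when adjusted over the list alone (mean 0.31, camera adjusted p = 0.000854; adjusted p = 0.19 with an estimated correlation). The integrin chain ITGAV rose from 29.5 ± 8.09 to 60.9 ± 2.88 FPKM and ICAM1 from 162 ± 16 to 302 ± 28.7 FPKM. Fatty acid synthesis genes rose in 5 of 11 cases, with 8 when adjusted over the list alone (mean 0.35, camera adjusted p = 8.91e-05; adjusted p = 0.135 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose from 439 ± 52.5 to 850.5 ± 4.31 FPKM and FADS2 from 273 ± 15.2 to 410.3 ± 34.4 FPKM. Cytokines and NF-kB targets rose in 11 of 23 cases and fell in 2, with 16 changed when adjusted over the list alone (mean 0.31, camera adjusted p = 0.00022; adjusted p = 0.258 with an estimated correlation), and IL6 rose from 206 ± 32.7 to 322 ± 9.3 FPKM.

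Mesenchymal markers rose in 7 of 14 cases in siDDX5 and fell in 2, with 9 changed when adjusted over the list alone (mean 0.35, camera adjusted p = 0.002; adjusted p = 0.271 with an estimated correlation). Smooth muscle actin, ACTA2, rose from 43.3 ± 5.45 to 134 ± 9.84 FPKM, while vimentin, VIM, fell from 2007 ± 81 to 1346 ± 50.9 FPKM. Basal and myoepithelial markers rose in 3 of 4 tested genes, also 3 when adjusted over the list alone (mean 0.85, camera adjusted p = 0.00391; adjusted p = 0.171 with an estimated correlation), and these were ACTA2, TAGLN and TP63. Apoptosis regulators rose in 7 of 19 cases and fell in 1, with 11 changed when adjusted over the list alone (mean 0.20, camera adjusted p = 0.0153; adjusted p = 0.286 with an estimated correlation), including PMAIP1 (16.4 ± 3.56 to 36.1 ± 4.33 FPKM). TGF-beta targets rose in 3 of 17 cases and fell in 1, with 4 changed when adjusted over the list alone (mean 0.16, camera adjusted p = 0.034; adjusted p = 0.442 with an estimated correlation), and 0 of these 4 gene calls held under all alternatives. ER stress and ATF4 targets rose in 7 of 24 cases and fell in 2, with 10 changed when adjusted over the list alone (mean 0.11, camera adjusted p = 0.0392; adjusted p = 0.271 with an estimated correlation). The TGF-beta call ended without siControl replicate 2 (adjusted p = 0.0501) or siDDX5 replicate 2 (0.0899), and the ER stress call without siControl replicate 3 (0.0573), siDDX5 replicate 2 (0.0719) or siDDX5 replicate 3 (0.0541). With no trend (0.0546 and 0.0598) and without the 3 libraries that deviate together (0.0902 and 0.0737) the TGF-beta and ER stress calls both ended, the former also in fry (0.163) and the latter with no filter (0.0514). The ER stress mean was 0.18 after upper quartile and 0.17 after sum scaling with or without 5S and 5.8S rRNA, and the TGF-beta mean 0.10 without the 3 libraries.

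Across all genes, 2593 of 13081 changed in siDDX5, 1112 higher and 1481 lower, so 42.9% were higher. That share was 59.5% after scaling to one upper quartile, 61.4% after scaling to one sum, 58.0% with 5S and 5.8S rRNA left out of that sum and 53.04% after quantile normalisation, so the scaling decides which direction is the more frequent. Changes of at least 2-fold numbered 281, with 223 higher and 58 lower, and 181 among genes with a mean of at least 5 FPKM. The count fell to 1403 without siControl replicate 1, 1506 without siDDX5 replicate 1 and 1507 without siDDX5 replicate 3, and to 1641 after scaling to one sum, but to 2300 with the rRNA left out of the sum.

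**Figure D2:**
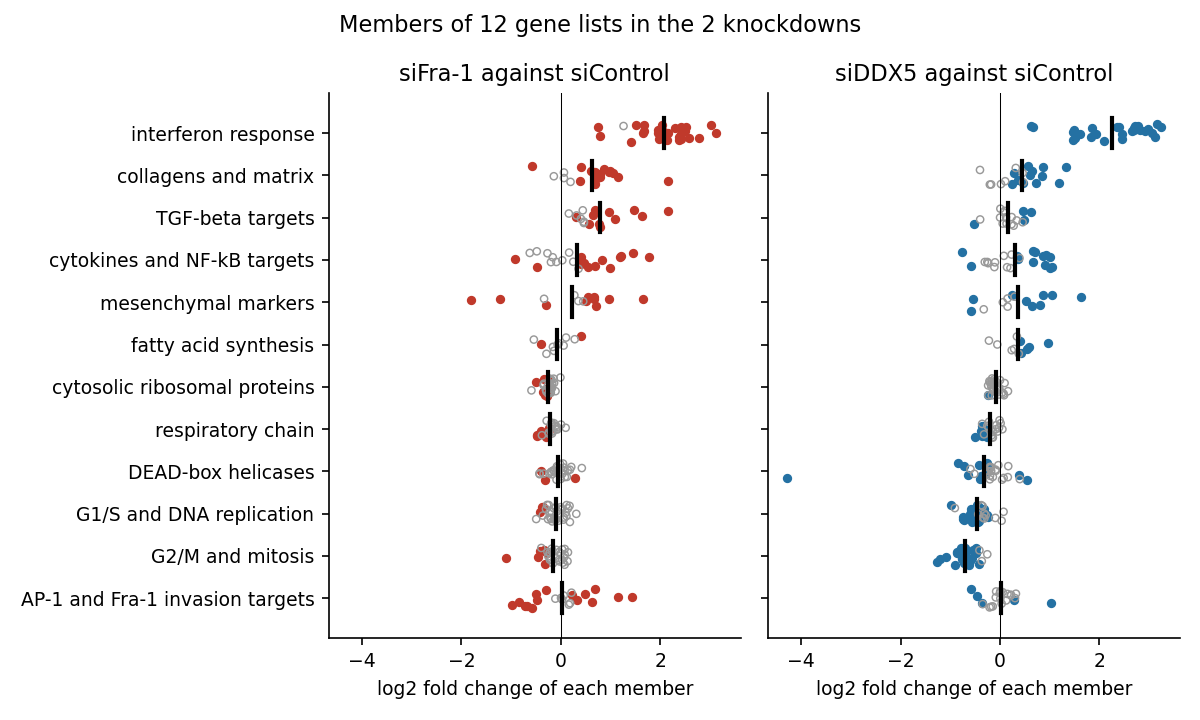
Log2 fold changes of the members of gene lists in each knockdown against siControl. Filled points passed the test, open points did not, and the black bar is the mean of the list; the interferon response averaged 2.07 in siFra-1 and 2.26 in siDDX5, and the G2/M list -0.16 and -0.70.

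The knockdowns were also compared with each other, which tests the difference directly because the shared control drops out. ACTA2 (ENSG00000107796, chromosome 10, 90694831 to 90751147) stood at 134 ± 9.84 FPKM in siDDX5 and 18.4 ± 2.79 FPKM in siFra-1, 7.15-fold apart (n = 3 per group, adjusted p = 2.12e-06), and TAGLN at 198 ± 20.6 and 32.0 ± 4.6 FPKM. KRT18 and KRT8 went the other way: KRT18 (ENSG00000111057) was at 2.94 ± 0.264 FPKM in siDDX5 and 15.4 ± 1.56 FPKM in siFra-1 (adjusted p = 5.01e-05), and KRT8 at 1.48 ± 0.263 and 7.72 ± 1.63 FPKM (adjusted p = 0.000228). The inflammatory cytokine IL1B was 2.42-fold higher in siDDX5, at 24.0 ± 0.868 FPKM. Cyclin D1, CCND1, was at 34.2 ± 3.79 FPKM in siDDX5 and 68.1 ± 5.11 FPKM in siFra-1 (adjusted p = 0.000349).

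Of 32 G2/M and mitosis genes, 28 were lower in siDDX5 than in siFra-1 and 0 higher, with 32 different when adjusted over the list alone (mean -0.54, camera adjusted p = 4.1e-14; adjusted p = 0.254 with an estimated correlation), among them KIF20A and CENPF. G1/S and DNA replication genes were lower in 17 of 33 cases and higher in 1, with 21 when adjusted over the list alone (mean -0.35, camera adjusted p = 8.46e-06; adjusted p = 0.254 with an estimated correlation). TGF-beta targets were lower in 8 of 17 cases, also 8 when adjusted over the list alone (mean -0.63, camera adjusted p = 7.93e-05; adjusted p = 0.277 with an estimated correlation), including TGFBI at 86.3 ± 5.64 against 212 ± 5.64 FPKM. Fatty acid synthesis genes were higher in 5 of 11 cases, with 6 when adjusted over the list alone (mean 0.43, camera adjusted p = 1.06e-05; adjusted p = 0.0799 with an estimated correlation). Cholesterol synthesis genes were higher in 6 of 23 cases and lower in 1, with 8 when adjusted over the list alone (mean 0.20, camera adjusted p = 0.000528; adjusted p = 0.0871 with an estimated correlation), including SREBF2. Basal and myoepithelial markers were higher in 3 of 4 tested genes, also 3 when adjusted over the list alone (mean 1.51, camera adjusted p = 0.000203; adjusted p = 0.121 with an estimated correlation), and with no filter on low values, which adds members near the floor, the mean was 0.74.

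Cytosolic ribosomal protein genes were higher in siDDX5 than in siFra-1 in 3 of 32 cases, with 0 when adjusted over the list alone (mean 0.17, camera adjusted p = 1.06e-05; adjusted p = 0.486 with an estimated correlation), and 0 of these 3 gene calls held under all alternatives. ER stress and ATF4 targets were higher in 8 of 24 cases and lower in 3, with 13 when adjusted over the list alone (mean 0.11, camera adjusted p = 0.0357; adjusted p = 0.321 with an estimated correlation). Among the interferon response genes 3 of 27 were higher and 1 lower, with 4 when adjusted over the list alone (mean 0.19, camera adjusted p = 0.00197; adjusted p = 0.689 with an estimated correlation), and 0 of these 4 gene calls held under all alternatives. Heat shock genes were higher in 1 of 13 cases, also 1 when adjusted over the list alone (mean 0.10, camera adjusted p = 0.0314; adjusted p = 0.254 with an estimated correlation), and that gene call did not hold under all alternatives. Without siFra-1 replicate 1 the calls of the interferon (mean 0.047, adjusted p = 0.135), ER stress (mean 0.055, adjusted p = 0.135) and heat shock (adjusted p = 0.055) lists ended, and the heat shock call also ended without siFra-1 replicate 2 (0.0573), where the interferon mean was 0.31. After quantile normalisation the ER stress (0.121) and heat shock (0.22) calls ended, and in fry those of the ribosomal protein (0.108), interferon (0.345) and ER stress (0.0869) lists. With no trend the ER stress and heat shock lists each had an adjusted p of 0.0525, scaling to one sum gave the ER stress list 0.0545 (still called with 5S and 5.8S rRNA left out of the sum), and array weights and leaving out the 3 libraries gave the heat shock list 0.0664 and 0.0617. Upper quartile and sum scaling gave means of 0.18 and 0.17 for the ER stress list and 0.18 and 0.17 for the heat shock list, and quantile normalisation 0.11 for the ribosomal protein list.

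In total 2105 genes differed between the knockdowns, 778 higher and 1327 lower in siDDX5, so 37.0% were higher; the share was 55.1%, 51.8% and 51.9% after upper quartile, sum and quantile scaling, and 33.8% with 5S and 5.8S rRNA left out of the sum. Differences of at least 2-fold numbered 207, with 99 higher and 108 lower, and 107 among genes with a mean of at least 5 FPKM. The count fell to 1365 without siFra-1 replicate 1, 1209 without siFra-1 replicate 3, 1270 without siDDX5 replicate 1 and 1148 without siDDX5 replicate 3, and to 1352 after scaling to one sum (2136 without the rRNA), and it rose to 3845 with array weights.

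The series names DDX5 as a coactivator of Fra-1, so the genes that moved in both knockdowns were counted. In both, 629 genes rose and 358 fell, which is 43.7% of the genes higher in siFra-1 and 33.5% of those lower. Independent lists of these sizes would share 122.4 and 120.9 genes, with 253.8 in opposite directions, but these lists share their controls. Large rises in both knockdowns were those of OAS2, CXCL10, IFIT1, IFI44L and OAS1, with OAS2 at 81.1 ± 8.5 FPKM in siFra-1 and 83.2 ± 6.67 FPKM in siDDX5. GEM fell from 34.2 ± 2.43 FPKM to 10.3 ± 1.43 and 14.997 ± 1.74 FPKM, the aldehyde oxidase AOX1 from 7.61 ± 1.25 to 2.73 ± 0.269 and 3.04 ± 0.49 FPKM and TMEM184B, whose 3′ UTR held GAGTAGC, from 24.0 ± 2.93 to 10.8 ± 0.433 and 8.30 ± 0.999 FPKM. In opposite directions 40 genes moved. These included ACTA2, TAGLN and CCDC190, which fell in siFra-1 and rose in siDDX5, the last without a call in siDDX5 when the 3 libraries that deviate together were left out (adjusted p = 0.083). At least 2-fold changes in the same direction in both knockdowns numbered 143 genes, 135 higher and 8 lower, and 24 of the 143 were on the interferon list. Without that list the genes changed in the same direction numbered 961. Of 22 tested AP-1 and Fra-1 invasion targets, 2 rose, 3 fell and 17 did not pass in siDDX5, against 7, 8 and 7 in siFra-1. Their mean log2 fold change in siDDX5 was 0.0136 (camera adjusted p = 0.846).

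Fold changes in the knockdowns correlated across genes, which are not independent replicates (Pearson r 0.587, Spearman rho 0.537). Because 3 control libraries enter both comparisons, groups with no change simulated with the same controls already gave an r of 0.5001 and a rho of 0.467. The simulated covariance averaged 0.0210 against 0.111 measured. The same simulations gave 0 genes changed in the same direction, but groups with no change yield almost no calls, so that 0 sets no expectation for the overlap. With 1 control set against one knockdown and the other 2 against the other, the 6 ways gave an r of 0.301 to 0.450, a covariance of 0.0695 to 0.0998 and 264 to 486 genes changed in the same direction. Such splits also leave fewer controls per comparison, and none leaves 2 on each side, so part of the overlap can come from sharing them. The 987 genes changed in the same direction became 512 without siControl replicate 1, 622 without siFra-1 replicate 3 and 594 without siDDX5 replicate 3. The 40 opposite genes became 19 without siControl replicate 1, 23 without siControl replicate 2, 26 without siFra-1 replicate 1 or 3, 22 without siDDX5 replicate 1 or 2 and 18 without siDDX5 replicate 3. Same-direction and opposite genes numbered 628 and 19 after scaling to one sum, 973 and 44 with 5S and 5.8S rRNA left out of the sum, 1606 and 132 with a GC trend removed and 374 and 11 without the 3 libraries that deviate together, and 26 were opposite with only the 2 groups compared.

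**Figure D3:**
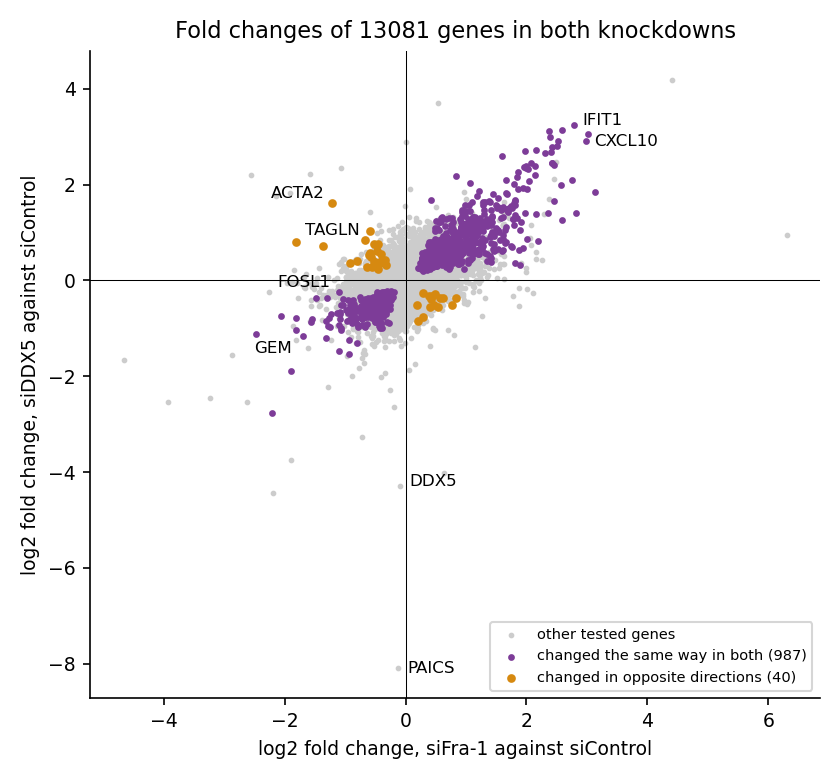
Log2 fold change of each tested gene in siFra-1 (x axis) and in siDDX5 (y axis), both against siControl. Across genes r was 0.587, and 987 genes changed in the same direction against 40 in opposite directions; the place of PAICS, listed at 0 in siDDX5, depends on the value added before taking logs.

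**Figure D4:**
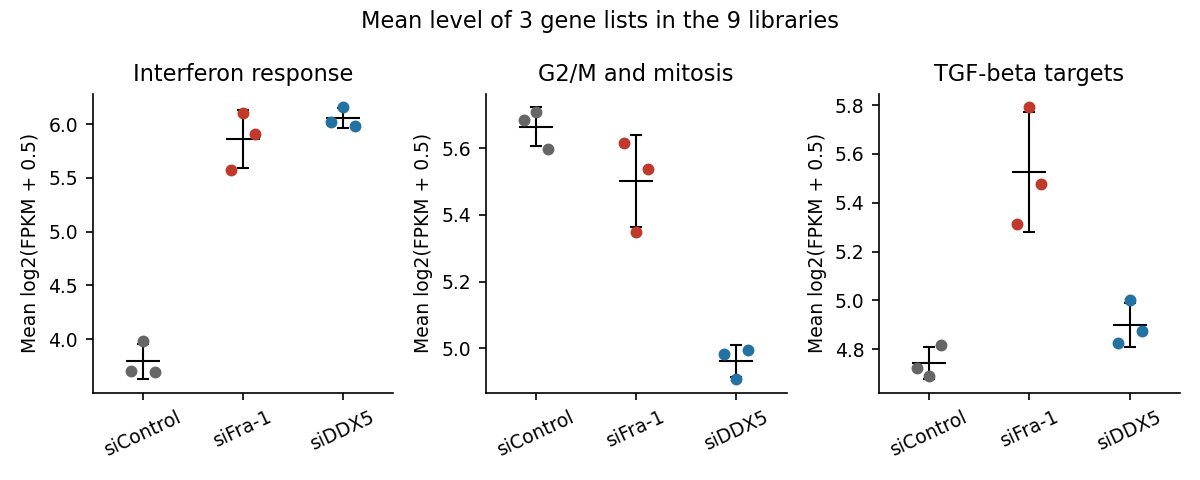
Mean log2 level of gene lists in each of the 9 libraries. All siFra-1 and siDDX5 libraries lay at or above 5.57 for the interferon response, and the siControl libraries at or below 3.985.

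Transcript shares within genes were compared because DDX5 is an RNA helicase and the files quantify transcripts. Of 22364 transcripts of 7193 genes, limma called 0 in siFra-1 and 0 in siDDX5, and a logit scale also gave 0 in each. At an unadjusted p under 0.05 there were 1826 (8.16%) and 2223 (9.94%), and the smallest adjusted p-values were 0.0814 and 0.1. The largest shift in a named gene was in ZBED1, where transcript ENST00000381222 averaged 16% ± 11.1 (SD, n = 3) of the gene in siControl and 87.8% ± 18.7 in siDDX5 (limma adjusted p = 0.298). Among genes with a mean of at least 20 FPKM the counts were 3 and 11. Without siControl replicate 3 they were 123 and 113, without siControl replicate 1 they were 1 and 2, without siFra-1 replicate 1 they were 1 and 3, and without siFra-1 replicate 2 they were 2 and 0.

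Most markers of cell types other than the tumour line were near the floor. Of the leukocyte, endothelial, and erythroid and liver lists 1 member each was tested, and the untested members reached at most 1.34, 0.882 and 0.556 FPKM. The leukocyte list's tested member, the lysosomal CD68, fell from 22.4 ± 1.7 to 13.8 ± 1.69 FPKM in siFra-1 (adjusted p = 0.00405).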

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

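Both tests of the interferon response, the test of the interferon list alone, the tests of 7-mers without a GC trend and of how many pass the shuffles, and the test of sequencing depth were chosen only after the result was seen. The tests of Alu repeats and of the axis shared by replicates were also built on patterns first seen in these data. Against the shared control 40 genes changed in opposite directions; all of them also passed the direct test between the knockdowns, which this choice of genes all but fixes and which adds no support. ACTA2 was 2.838 higher on the log2 scale in siDDX5 than in siFra-1, TAGLN 2.612 and CCDC190 2.099. Of the gene lists, basal and myoepithelial markers differed by a mean of 1.51 over 4 of 9 members, or 0.74 with no filter on low values, fatty acid synthesis by 0.426, cholesterol synthesis by 0.197, interferon response by 0.192, cytosolic ribosomal proteins by 0.167, ER stress and ATF4 targets by 0.106 and heat shock by 0.103. TGF-beta targets were lower in siDDX5 by a mean of -0.626, G2/M and mitosis by -0.539 and G1/S and DNA replication by -0.351. With an estimated correlation none of these list differences passed (adjusted p from 0.0799 to 0.689). Without siFra-1 replicate 1 the interferon difference was 0.047 and the ER stress difference 0.055, and without siFra-1 replicate 2 the interferon difference was 0.31. Outside the genes tested, 5S and 5.8S rRNA genes summed to 136200 FPKM in siFra-1 replicate 1 and to 0 in the other 8 libraries.

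The interferon response rose in both knockdowns. The gap between the lowest knockdown library (5.573) and the highest control library (3.985) was 5.44 times the range of the 3 controls, which argues against spread between the shared controls as its source. The siControl libraries received an siRNA too, so a response common to all siRNAs would not show against them. A response to both targeting duplexes and not to the control duplex cannot be told apart from loss of the targets. The mean difference of the list between the knockdowns was 0.192. The bound for this test was set after the rises were seen, so it could not have excluded such a response. What keeps it open is that each target has 1 siRNA group here. There is also no untransfected group to show a response shared with the control siRNA. Without the 27 genes of the list the covariance of the fold changes was 0.1007, still 0.0797 above the simulated one, against 0.1109 with them. Leaving out so few of 13081 genes could hardly bring it to the simulated value. Interferon-induced genes off the list, such as CXCL10, stayed in, so a wider interferon response in the shared change was not tested.

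In siFra-1 the 3′ UTR 7-mer with the most negative statistic was GAGTAGC (t = -10.351 over 895 genes, lowest of 100 shuffles -4.838) and in siDDX5 it was GTCCTTG (t = -7.431 over 1019 genes, lowest of 100 shuffles -4.882), with t = -10.541 and -7.066 once a GC trend was removed from the fold changes. Each occurs in the target's own mRNA, as do 9.4% and 14.6% of the 15218 7-mers tested. Both thus met the criterion set beforehand, a leading 7-mer beyond all 100 shuffles that occurs in the target mRNA. In siDDX5 the next 7-mer, TGTCCTT (t = -5.672), overlaps GTCCTTG and also occurs in the DDX5 mRNA. In the other knockdown they had t = -1.112 and -1.547. Of 14 7-mers beyond the shuffles in siDDX5, 8 neither occur in the DDX5 mRNA nor share 5 bases in a row with GTCCTTG. These were led by GGCCTGG (t = -5.667). With the GC trend removed, 2 of 5 7-mers beyond the shuffles were of this kind, led by GGCGGGT (t = -5.196). Passing the shuffles alone therefore marks no seed. GAGTAGC lay in 14.59% of the 891 genes lower in siFra-1 against 8.2% of all (Fisher p = 2.99e-11), and in 22 of 69 lower at least 2-fold (Fisher p = 1.38e-08). GTCCTTG lay in 11.95% of 1347 genes lower in siDDX5 against 9.33% (Fisher p = 0.000653). For enrichment there it ranked 1 among all 7-mers tested (one-sided Fisher p = 0.000359). The lowest such p of a 7-mer not overlapping it was 0.000898 (GGCCTGG). GAGTAGC was rarer among the same genes (5.49% against 8.2%, Fisher p = 6.61e-05). A two-sided p of this size thus arises without a seed match, though here in the other direction. Among genes lower at least 2-fold in siDDX5, GTCCTTG lay in 5 of 36 (Fisher p = 0.38) and ranked 1067 for enrichment. Seed matches of the siRNAs, whose sequences are not given in the sources used here, are a candidate explanation for a minority of the genes that fell in siFra-1, such as CDKN2C, ANAPC13 and CAP2, while for siDDX5, TOMM34, AK3 and IRAK1 included, it stays open. For siFra-1, Alu repeats as the sole source of the GAGTAGC effect were argued against. The most negative of 5 other 7-mers, all from a single Alu stretch that does not overlap GAGTAGC, reached t = -2.87. Of the Alu 7-mers that overlap it, AGTAGCT had t = -8.616 over 1472 genes. GTAGCTG had t = -5.313 over 1432 genes. Both lay beyond the shuffles and neither occurs in the FOSL1 mRNA. As they share most bases with GAGTAGC, they do not separate Alu repeats from a seed match. GAGTAGC had t = -3.025 over 410 genes where TGG follows it, as in Alu. Where TGG does not follow it, t was -11.14 over 412 genes.

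In each group 1 replicate deviated in the same way: siControl replicate 1, siFra-1 replicate 2 and siDDX5 replicate 2 lay low on an axis that held 32.51% of the spread within groups. Position on this axis fell with assigned depth (r = -0.813, exact permutation p = 0.0278 over 216 arrangements; Spearman rho -0.583, p = 0.125). It also followed GC content across genes (rho = -0.73), and the fold changes too ran with GC content (rho -0.208 in siFra-1, -0.324 in siDDX5 and -0.13 between the knockdowns), so depth and a GC bias of library preparation may each contribute. Whether transcript length (rho = 0.144) plays a part is not decided, as the value lies between the bounds set for an effect and for none. Mean loadings were -0.766 SD for TGF-beta targets, -0.582 for collagens and matrix, -0.467 for the interferon response and 0.42 for G2/M, so lists reported as changed also move along this axis; no biological explanation was tested.

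The splits of the 6 libraries of a comparison number 10, the real one included, too few for a share under 0.05. Every other split mixes libraries of both groups, which moves a real difference into the spread within groups. Their low gene counts are therefore no measure of what unchanged groups would give. The real splits gave 2508, 2593 and 2105 changed genes, against at most 4, 2 and 1 in the other splits, and 399, 281 and 207 genes changed at least 2-fold, against at most 4, 2 and 1; in each case 1 of the 10 splits was as large. For gene lists the real counts of 12, 15 and 10 stood against at most 13, 15 and 8, with 2, 2 and 1 splits as large. For isoform shares the real counts of 0 and 0 stood against at most 2 and 2, and all 10 splits were as large.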

How the results depend on the processing

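The GC correction and leaving out the 3 libraries that deviate together, like 2 further settings on genes listed at 0 or in pieces 1 that takes the targeted genes out of the lists, 1 that splits the controls and 1 that leaves rRNA out of the sum, were tests chosen only after the data were seen. In every alternative but an estimated correlation and fry, 8 of 12, 13 of 15 and 7 of 10 list calls stayed past the threshold in siFra-1, siDDX5 and between the knockdowns. Of the called genes that the naming rule took, over all lists, 84, 78 and 68 stayed past it in every alternative run for genes and 42, 44 and 36 did not.

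In what follows counts are for siFra-1, siDDX5 and the difference between them. Without the 3 libraries, which leaves fewer samples, they were 1191, 1112 and 1132, with 374 genes changed in the same direction and 11 in opposite directions. A mean of at least 5 FPKM, which tests fewer genes, gave 251, 181 and 107 genes changed at least 2-fold. Scaling to one sum gave 1716, 1641 and 1352, with 628 in the same and 19 in opposite directions. With 5S and 5.8S rRNA, above 0 in siFra-1 replicate 1 alone, left out of the sum these were 2502, 2300, 2136, 973 and 44. That rRNA thus accounts for most of the fall. Array weights gave 2907, 3019 and 3845. The GC correction gave 3672, 3865 and 3530, with 1606 and 132 in the same and opposite directions. Only the 2 groups compared gave 26 opposite. With an estimated correlation 0, 0 and 0 lists were called, and fry called 20 in siFra-1. Among genes of at least 20 FPKM, 3 and 11 isoform shares changed. Beyond sample or gene numbers, the cause was not tested.

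Leaving out 1 library gave 1415 to 2412, 1403 to 2802 and 1148 to 2138 changed genes, 512 to 1057 in the same direction, 18 to 42 in opposite directions, and 0 to 123 and 0 to 113 isoform shares.

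Reversals were confined to FOS and JUN members that did not pass. JUND turned in siFra-1 (0.01525) and FOSB in the difference (-0.0003497) after scaling to a sum without the rRNA. JUND turned with the GC correction in siFra-1 (0.03194), siDDX5 (0.2578) and the difference (0.2258). It turned without the 3 libraries in siDDX5 (0.03456) and the difference (0.209), and in the difference after upper quartile (0.06428), sum (0.05233) and quantile (0.08112) scaling and array weights (0.1649). FOSB turned without the 3 libraries in siDDX5 (-0.001627) and the difference (-0.08654). Leaving out 1 library, JUND ran from -0.2748 to 0.06948 in siFra-1, -0.1617 to 0.02661 in siDDX5 and -0.1433 to 0.201 in the difference. FOSB ran from -0.01345 to 0.2932 and -0.1019 to 0.2047, JUNB from -0.1846 to 0.273 and -0.8515 to 0.04425 in the latter comparisons. JUN ran from -0.005754 to 0.08569 in siDDX5 and FOSL2 from -0.00321 to 0.1076 in the difference. The cause was not tested.

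With siFra-1 set against siControl 1, 2 or 3 alone and siDDX5 against the other 2 controls, 486, 407 and 327 genes changed in the same direction and 12, 32 and 22 in opposite directions, and r was 0.4498, 0.3006 and 0.3528. With siDDX5 against siControl 1, 2 or 3 alone they were 480, 329 and 264, then 26, 12 and 17, and r was 0.3408, 0.4046 and 0.3569. How much of the fall comes from having fewer controls was not tested.

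The replicate block gave 1769, 1780 and 1478 changed genes in siFra-1, siDDX5 and the difference, with 651 in the same and 22 in opposite directions. After removal of group means, same-numbered libraries correlated at -0.286 to 0.0972 between siControl and the knockdowns and at 0.0127 to 0.336, all positive, between the knockdowns. Not every library correlated best with its own number, so the pairing was not used in the reported comparisons.

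What depth limits was not tested. At the measured spread and 3 libraries per group, simulated log2 changes of 0.5 were recovered in 26.9% of genes.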

Other observations

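The grouping of genes by the start of their symbols was chosen only after the data were seen, and gave 192 families. In siFra-1 the mitochondrial ribosomal MRPL genes fell in 11 of 48 cases, with 0 higher (mean log2 fold change -0.23, camera adjusted p = 7e-05; adjusted p = 0.632 with an estimated correlation). In siDDX5 they fell in 17 of 48 cases (mean -0.27, camera adjusted p = 2.43e-05; adjusted p = 0.671 with an estimated correlation), and the RNA polymerase POLR genes fell in 9 of 30 cases (mean -0.31, camera adjusted p = 0.00101; adjusted p = 0.57 with an estimated correlation). HAUS genes of the augmin complex fell in 5 of 8 cases in siDDX5 (mean -0.48, camera adjusted p = 0.00502; adjusted p = 0.57 with an estimated correlation). None of these family means changed sign under the 3 scaling alternatives.

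Some expressed genes were listed at 0 in some libraries and not in others. BECN1 and PSME3 were at 0 in siControl replicate 1 and siFra-1 replicates 1 and 2. In all, 17 tested genes with a median of at least 5 FPKM had a 0, PAICS among them.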
